A study of Arabidopsis thaliana with 18 samples.

How the data were processed

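The measurements were poly(A)-selected RNA-seq counts from whole rosettes of Arabidopsis thaliana (ecotype Columbia-0). Each library came from a pool of 5 rosettes from different pots, harvested at 18 days under a long-day photoperiod, per the labels. The 18 libraries covered 6 genotypes with 3 libraries each: wild type, ref5-1, ref2-1, med5a-1 med5b-1, ref5-1 med5a-1 med5b-1 and ref2-1 med5a-1 med5b-1. In what follows med5 stands for med5a-1 med5b-1. Libraries were stranded and read on an Illumina HiSeq instrument, per the labels. Samples were grouped by the genotype in their labels, and replicate numbers come from the same labels.

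The deposited table holds raw read counts per gene as the authors made them, with 1 column per library and no normalization. Trimmomatic, TopHat2 2.1.0, HTSeq 0.6.1 and edgeR were used with the TAIR10 build, per the submitters' processing notes. Their options, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping gene on the opposite strand cannot be told apart. Reads that fit several places equally well were left out of the gene counts. Genes with near-identical copies therefore carry uncertain counts, among them KIN1 and COR6.6, CYP79F1 and CYP79F2, the LHCB1 and LHCB2 genes, the RBCS genes and the PAI genes.

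The table has 33602 gene IDs and 5 summary lines that are not genes. The summary lines stayed out of library sizes and tests. Reads in no annotated feature made up 0.775% to 1.44% of a library, ambiguous reads 0.648% to 1.37% and reads with several alignments 3.71% to 25.3%. Gene counts per library ran from 19578169 to 33193849, and 22002 to 22606 genes had at least 1 count. At the lowest depth a CPM (a count scaled to library size) of 1 equals about 19.58 counts, so folds against genes near 0 CPM are imprecise. Symbols came from the file IDs matched to a TAIR10.1 gene table, which held 32835 of the IDs. That table was used for names and neighbouring genes alone, and no coordinates are given because its assembly differs in name from TAIR10. Of 309 list members, 242 had the table's symbol, 46 were among its synonyms and 21 carry a symbol not used in it.

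Counts were tested in edgeR 4.0.16 under R 4.3.3. Libraries were scaled by TMM, genes were filtered by filterByExpr on the genotypes, and 19897 genes remained. A robust quasi-likelihood negative binomial model with 1 coefficient per genotype was fitted to all 18 libraries, so that every comparison shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values used the TMM-scaled library sizes. The series design describes biological triplicates. The p-values measure the spread between these libraries. There were 8 comparisons of pairs of genotypes and 2 interactions, each asking whether the effect of ref5-1 or ref2-1 differs between plants with and without functional MED5.

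For groups of genes, 23 lists were fixed together with the test, the design and the alternatives before the data were examined. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists within a comparison. For each list the number of called members is given over all tested genes and adjusted over the list alone. Of all 230 list tests, 105 passed, and 3 of them also with an estimated correlation. Those were the auxin response list in ref5-1 against wild type, in ref5-1 med5 against med5 and in ref5-1 against ref2-1. The rule for named genes was also fixed in advance. It takes the targeted genes, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the higher genotype and no overlap between libraries, and up to 4 called members of each list with the smallest adjusted p. Members of this set are left out for length, and genes outside it are mostly given as CPM alone. Exceptions with test results include ARR6 and RR16 in ref5-1 against wild type and the neighbours of AT3G01345 and AT5G35935, which were chosen after the results were seen.

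The scripts were tested on simulated data. Counts were drawn from the mean of each gene over all 18 libraries and the real library sizes, with 200 genes changed. The changed genes were picked among those with a mean of at least 1 CPM. No other gene differed between genotypes, so the shares that follow hold for such data alone. For ref5-1 against wild type (19740 genes), edgeR recovered 59.7% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold, and 4.73% of its calls were unchanged genes. For the interaction of ref5-1 with med5 (19735 genes) the shares recovered were 26.9%, 67.2% and 90.9%, and 3.15% of calls were unchanged genes. DESeq2 1.42.0 made 13.8% and 14.5% of its calls on unchanged genes in the same simulations. Those runs used the 19897 filtered genes and its default level for its own filtering. The DESeq2 alternative below used all genes with counts and another level, so these shares do not carry over to its counts. Alternatives were DESeq2, RLE scaling, no filter on low counts, a fit to the compared libraries alone, the replicate number as a block, a minimum absolute log2 fold change of 1 and leaving out each library in turn. For the lists they were an estimated correlation, the fry test and the block. Thinning all libraries to the lowest depth, leaving out the third libraries of wild type and med5 together, and leaving out each library in the list tests were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.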

Results

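RNA was counted in whole rosettes of 6 Arabidopsis genotypes with 3 libraries each. The ref5-1 mutant carries a missense allele of CYP83B1 (AT4G31500), a cytochrome P450 of indole glucosinolate synthesis. The ref2-1 mutant lacks function of CYP83A1 (AT4G13770), its counterpart in aliphatic glucosinolate synthesis. Both mutants accumulate less phenylpropanoid product than wild type. MED5A (AT3G23590) and MED5B (AT2G48110) encode subunits of the Mediator complex, which links transcription factors to RNA polymerase, and the triple mutants join each glucosinolate allele with the med5 alleles. The comparisons ask which transcripts each glucosinolate lesion alters and which of these changes need MED5. Libraries held 19578169 to 33193849 gene counts, and the range within ref5-1 med5 spanned both ends. Values per gene are CPM as mean ± SD over 3 libraries, and log2 fold changes are given ± SE.

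**Figure D1:**
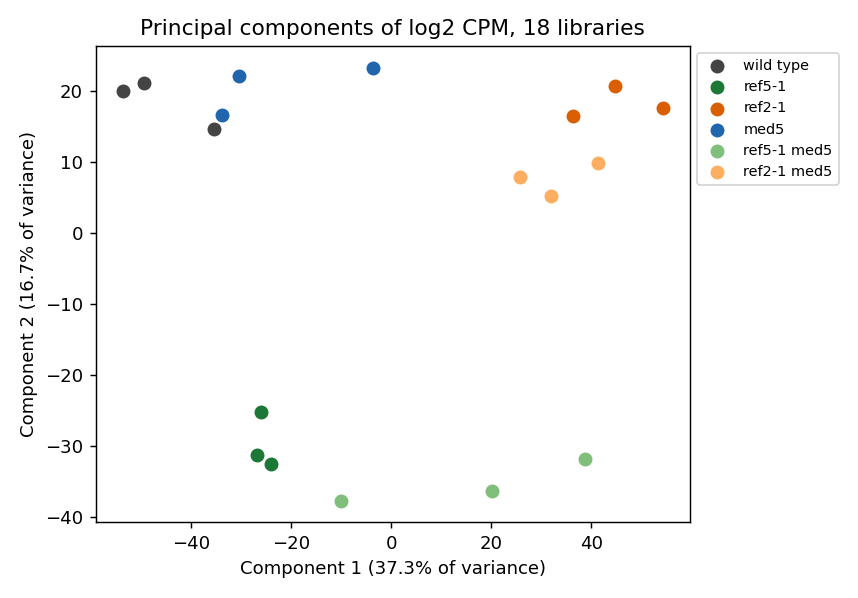
Principal components of log2 CPM over the 19897 tested genes, with component 1 (37.3% of the variance) on the horizontal axis and component 2 (16.7%) on the vertical axis. Each point is 1 of the 18 libraries, coloured by genotype, and the libraries with the ref5-1 allele lie below 0 on component 2 while the others lie above it.

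The targeted genes were read first. CYP83A1 (AT4G13770) fell to 123 ± 6.06 CPM in ref2-1 from 402 ± 58.8 CPM in wild type (log2 fold change −1.71 ± 0.11, adjusted p = 2.88e-08), and to 138 ± 17.2 CPM in ref2-1 med5 from 467 ± 59.4 CPM in med5 (log2 fold change −1.75 ± 0.11). MED5B (AT2G48110) fell in med5 to 6.68 ± 0.378 CPM from 24.5 ± 1.03 CPM (log2 fold change −1.87 ± 0.091, adjusted p = 3.11e-10), with 7.43 ± 0.460 CPM in ref5-1 med5 and 8.10 ± 0.446 CPM in ref2-1 med5. MED5A (AT3G23590) was at 49.5 ± 3.57 CPM in wild type, 31.6 ± 2.39 CPM in med5 (log2 fold change −0.65 ± 0.092, adjusted p = 0.00139), 38.7 ± 1.85 CPM in ref5-1 med5 and 26.7 ± 3.05 CPM in ref2-1 med5. The ref5-1 lesion changes the protein, so the CYP83B1 (AT4G31500) level, 254 ± 82.9 CPM in wild type and 247 ± 21.6 CPM in ref5-1, checks no label. Every library had the CYP83A1 and MED5B level of the genotype in its label, and MED5A did not separate the libraries in this way, with 38.7 CPM in ref5-1 med5 and 39.1 CPM in ref2-1.

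Compared with wild type, ref5-1 rosettes had more transcript of Kelch-domain F-box genes, of auxin-response genes and of cold and abscisic acid response genes. KFB39 (AT2G44130), an F-box protein that marks phenylalanine ammonia-lyase for degradation, rose 5.45-fold, from 11.9 ± 0.514 to 65.1 ± 11 CPM (adjusted p = 1.49e-09). KFB50 (AT3G59940), which acts on the same enzyme, rose 2.07-fold to 124 ± 19.5 CPM (adjusted p = 0.000249). Of the 5 measured F-box genes of this list, 3 were called higher (4 adjusted over the list alone; camera adjusted p = 3.78e-05, and adjusted p = 0.16 with an estimated correlation). KFB39 and KFB50 were known from work on these mutants when the list was fixed, so this count is not independent evidence. MYB4 (AT4G38620), a repressor of phenylpropanoid genes, rose 1.56-fold to 35.2 ± 4.94 CPM. The phenylpropanoid list itself did not pass as a group (camera adjusted p = 0.593) and went both ways. Of its 22 genes 4 were called higher (5 adjusted over the list alone), a count of 1 without wild type replicate 1, wild type replicate 2 or ref5-1 replicate 2 and 2 without ref5-1 replicate 1 or ref5-1 replicate 3. Another 2 were called lower (3 adjusted over the list alone), a count of 1 without wild type replicate 2, wild type replicate 3 or ref5-1 replicate 2. The flavonoid and anthocyanin list leaned up as a group (median log2 fold change 0.591, camera adjusted p = 2.72e-05, and adjusted p = 0.486 with an estimated correlation). Of its 22 genes 2 were called higher (7 adjusted over the list alone), a count of 0 to 13 with a library left out. The auxin conjugase genes GH3.1 (AT2G14960) at 3.41 ± 0.42, GH3.3 (AT2G23170) at 2.29 ± 0.18, GH3.5 (AT4G27260) at 2.17 ± 0.15 and GH3.6 (AT5G54510) at 1.48 ± 0.12 on the log2 scale were called higher. Of 19 auxin-response genes 11 were called higher (11 adjusted over the list alone; camera adjusted p = 2.24e-11, with adjusted p = 0.0244 under an estimated correlation). Stomatal lineage markers moved down, 2 of 5 genes called lower (3 adjusted over the list alone, camera adjusted p = 0.00625, and adjusted p = 0.164 with an estimated correlation). That count was 0 without wild type replicate 2 or ref5-1 replicate 1 and 1 without wild type replicate 3 or ref5-1 replicate 2. Root markers moved up, 1 of 2 measured genes called higher (2 adjusted over the list alone, camera adjusted p = 0.00906, and adjusted p = 0.164 with an estimated correlation).

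Of the cold and abscisic acid response genes 10 of 11 were called higher (11 adjusted over the list alone; camera adjusted p = 1.52e-13, and adjusted p = 0.0531 with an estimated correlation). Examples were KIN1 (AT5G15960) at 3.80 ± 0.54, COR15B (AT2G42530) at 2.91 ± 0.39, LTI30 (AT3G50970) at 2.63 ± 0.33 and RD29B (AT5G52300) at 3.05 ± 0.40, where the counts of KIN1 are uncertain because of its near-identical copy COR6.6. In the glucosinolate lists CYP79F2 (AT1G16400) at 0.69 ± 0.13, FMOGS-OX4 (AT1G62570) at 0.79 ± 0.11, CYP81F3 (AT4G37400) at 1.36 ± 0.18 and ESM1 (AT3G14210) at 1.15 ± 0.17 on the log2 scale were called higher. Counts of CYP79F2 are uncertain because of its near-identical copy CYP79F1. The aliphatic list passed with 5 of 26 genes higher (camera adjusted p = 0.000208, and 0.486 with an estimated correlation). That count was 2 to 6 with a library left out. The indole list had 2 of 18 higher (camera adjusted p = 0.017, and 0.626 with an estimated correlation). It did not pass without wild type replicate 1 or 2. The breakdown list, with 2 of 6 higher, did not pass (camera adjusted p = 0.121). The sulfate transporters SULTR2;1 (AT5G10180) and SULTR4;2 (AT3G12520) rose 1.38-fold and 1.53-fold. The sulfate assimilation list moved up as a group (camera adjusted p = 3.96e-05, and adjusted p = 0.345 with an estimated correlation), and 6 of its 18 genes were called (6 adjusted over the list alone), a count of 2 without wild type replicate 1, 2 without wild type replicate 2 and 2 without ref5-1 replicate 1. Further called genes were PR2 (AT3G57260), a pathogenesis-related glucanase (4.31 ± 0.78), the aldo-keto reductase AKR4C9 (AT2G37770) (1.95 ± 0.29), and BGLU23 (AT3G09260), a beta-glucosidase abundant in roots, at 383 ± 26.1 CPM against 128 ± 30 CPM. The salicylate list, which holds PR2, leaned up (camera adjusted p = 0.00923, and adjusted p = 0.637 with an estimated correlation). Of its 17 genes 2 were called higher (2 adjusted over the list alone), a count of 1 to 2 with a library left out. The lipid-transfer family gene AT4G15160 reached 8.34 ± 1.35 CPM from 0.293 ± 0.104 CPM. On the lower side, FSD1 (AT4G25100), an iron superoxide dismutase, fell from 354 ± 82.4 CPM to 74.6 ± 9.21 CPM (adjusted p = 0.0011). The cytokinin response regulator ARR15 (AT1G74890) fell 3.02-fold, the orphan gene QQS (AT3G30720) 3.26-fold, the expansin EXPA8 (AT2G40610) 2.23-fold, GASA6 (AT1G74670) 2.29-fold and MRD1 (AT1G53480) from 28.7 ± 0.871 CPM to 0.338 ± 0.284 CPM.

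In total edgeR called 1735 genes between ref5-1 and wild type, 1018 higher and 717 lower. The count was 914 without wild type replicate 1 and 716 without wild type replicate 2. A fit to the 6 compared libraries alone called 1057.

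**Figure D2:**
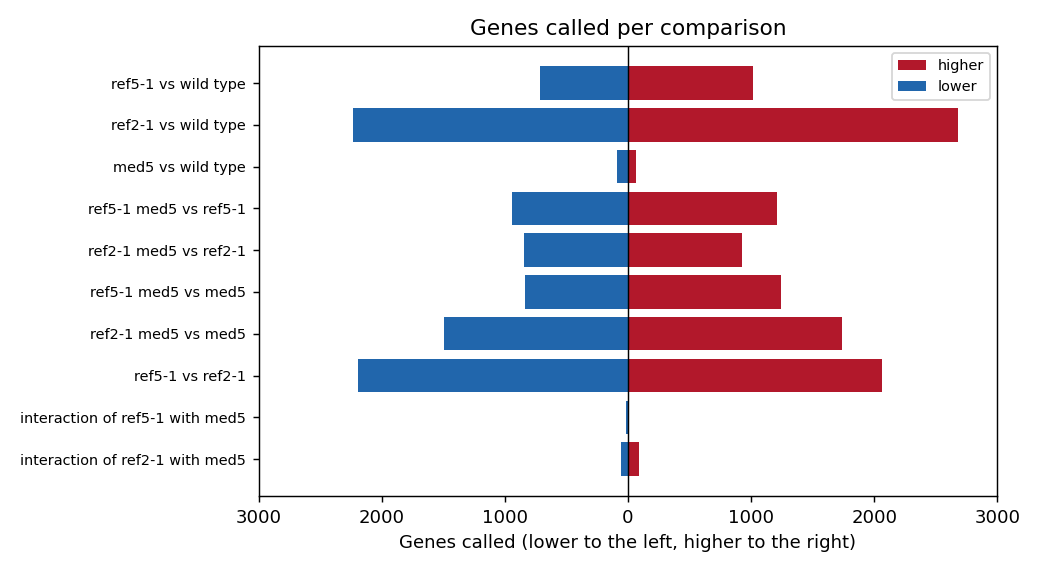
Numbers of genes called at an adjusted p under 0.05 in the 8 comparisons of pairs and the 2 interactions, with bars to the left for lower and to the right for higher. The ref2-1 against wild type bar, 2680 higher and 2235 lower, and the ref5-1 against ref2-1 bar, 2066 higher and 2192 lower, are the longest.

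Against wild type, ref2-1 rosettes had more transcript of salicylate defence genes and of aliphatic glucosinolate and sulfate assimilation genes, and less of phenylpropanoid genes. All 17 measured genes of the salicylate list were called higher (17 adjusted over the list alone; camera adjusted p = 1.16e-12, and adjusted p = 0.223 with an estimated correlation). PR1 (AT2G14610), the standard marker of systemic resistance, was at 245 ± 134 CPM against 0.280 ± 0.185 CPM in wild type (adjusted p = 0.000451), with log2 fold changes of PR2 at 6.76 ± 0.81, PR5 (AT1G75040) at 4.15 ± 0.44, SARD1 (AT1G73805) at 4.12 ± 0.60 and CBP60G (AT5G26920) at 4.21 ± 0.61. The receptor kinases CRK7 (AT4G23150) and WAK3 (AT1G21240) reached 15.9 ± 4.88 CPM and 11.2 ± 1.85 CPM. WRKY33 (AT2G38470), a transcription factor of defence, rose 5.11-fold, and the zinc-finger gene ZAT10 (AT1G27730) rose 4.19-fold, both on a list of rapid stress genes of which 3 of 5 were called (5 adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.228 with an estimated correlation). Of 26 aliphatic glucosinolate genes 21 were called higher (22 adjusted over the list alone; camera adjusted p = 1.96e-11, and adjusted p = 0.223 with an estimated correlation), including the chain-elongation genes MAM3 (AT5G23020) at 2.84 ± 0.23, BCAT4 (AT3G19710) at 1.41 ± 0.13 and IPMI2 (AT2G43100) at 1.29 ± 0.13. In that list 2 were called lower (2 adjusted over the list alone), a count of 1 without ref2-1 replicate 2. Sulfate assimilation genes rose too, 12 of 18 (15 adjusted over the list alone; camera adjusted p = 1.26e-06, and adjusted p = 0.228 with an estimated correlation), with APR3 (AT4G21990) at 1.00 ± 0.17, APR1 (AT4G04610) at 0.65 ± 0.13, APK2 (AT4G39940) at 0.65 ± 0.12 and SULTR1;2 (AT1G78000) at 2.21 ± 0.44.

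The F-box genes behaved in ref2-1 as a called group as well. KFB39 rose 5.47-fold to 65.4 ± 3.02 CPM (adjusted p = 1.42e-09), KFB50 1.94-fold and KFB01 (AT1G15670) 3.14-fold. These were 3 of 5 genes (4 adjusted over the list alone; camera adjusted p = 0.00294, and adjusted p = 0.228 with an estimated correlation), a count that is not independent evidence for the reason given above. Of 22 phenylpropanoid genes 12 fell (12 adjusted over the list alone) and 3 rose (camera adjusted p = 0.000374, and adjusted p = 0.228 with an estimated correlation). 4CL1 (AT1G51680), which activates coumarate, fell 1.68-fold to 94.8 ± 8.62 CPM (adjusted p = 3.25e-05), and the shikimate transferase HCT (AT5G48930) fell 1.73-fold. The risers were not all pathway enzymes: MYB4 represses the pathway (0.92 ± 0.093), and ALDH2C4 (AT3G24503) makes ferulate and sinapate (0.78 ± 0.085). The myrosinase TGG1 (AT5G26000) fell (−0.94 ± 0.21) and PEN2 (AT2G44490), an atypical myrosinase of defence, rose (0.64 ± 0.081). Auxin-response genes went down, IAA29 (AT4G32280) at −2.54 ± 0.19, IAA5 (AT1G15580) at −1.14 ± 0.16, HAT2 (AT5G47370) at −0.61 ± 0.08 and IAA3 (AT1G04240) at −0.49 ± 0.097, 5 of 19 in all (6 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.273 with an estimated correlation). That list test gave adjusted p = 0.0589 without ref2-1 replicate 1. Xylem and secondary wall markers moved down with the phenylpropanoid genes, 6 of 11 called lower (7 adjusted over the list alone; camera adjusted p = 0.000374, and adjusted p = 0.283 with an estimated correlation), a count of 3 without wild type replicate 3 and 2 without ref2-1 replicate 2. Of these CESA4 (AT5G44030) and IRX9 (AT2G37090) fell (−0.71 ± 0.15 and −0.79 ± 0.19), and in the stomatal lineage TMM (AT1G80080) and FAMA (AT3G24140) (−0.67 ± 0.10 and −0.41 ± 0.088; 2 of 5 called, 5 adjusted over the list alone; camera adjusted p = 0.00349, and adjusted p = 0.223 with an estimated correlation). The floral repressor FLC (AT5G10140) rose (1.66 ± 0.34), while SOC1 (AT2G45660) and SEP3 (AT1G24260) fell (−0.36 ± 0.091 and −1.67 ± 0.37). The clock genes TOC1 (AT5G61380) and GI (AT1G22770) were higher (0.84 ± 0.092 and 0.81 ± 0.13) and LHY (AT1G01060) lower (−0.58 ± 0.085). In edgeR 4915 genes were called, 2680 higher and 2235 lower.

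A direct test of ref5-1 against ref2-1 set the salicylate, auxin and cold responses of the mutants apart. PR1 was at 0.662 ± 0.0999 CPM in ref5-1 and 245 ± 134 CPM in ref2-1 (adjusted p = 0.000672), and 15 of 17 salicylate genes were lower in ref5-1 (16 adjusted over the list alone; camera adjusted p = 3e-10, and adjusted p = 0.264 with an estimated correlation), among them SARD1 at −3.31 ± 0.56, PAD4 (AT3G52430) at −2.64 ± 0.42 and PR5 at −2.39 ± 0.40. Auxin-response genes were higher in ref5-1, 15 of 19 (17 adjusted over the list alone; camera adjusted p = 1.03e-13, with adjusted p = 0.0104 under an estimated correlation), with IAA29 at 2.54 ± 0.19, GH3.5 at 2.33 ± 0.16, IAA19 (AT3G15540) at 1.68 ± 0.14 and GH3.6 at 1.52 ± 0.12. Of the 19 auxin-response genes 1 was called lower (1 adjusted over the list alone), a count of 0 without ref2-1 replicate 3. Cold and abscisic acid genes followed, 10 of 11 (10 adjusted over the list alone; camera adjusted p = 1.09e-10, and adjusted p = 0.119 with an estimated correlation), with KIN1 at 3.5 ± 0.53, RD29B at 2.90 ± 0.39, LTI30 at 1.97 ± 0.32 and COR47 (AT1G20440) at 1.51 ± 0.17. The galactinol synthase GolS2 (AT1G56600) and the phosphatase HAI2 (AT1G07430), both tied to drought, were higher by 21.7-fold and 10.4-fold. Aliphatic glucosinolate genes were lower in ref5-1 in 18 of 26 (19 adjusted over the list alone; camera adjusted p = 2.58e-07, and adjusted p = 0.272 with an estimated correlation), as BCAT4 at −1.19 ± 0.13, AOP2 (AT4G03060) at −1.05 ± 0.098 and BAT5 (AT4G12030) at −0.80 ± 0.084, while 3 were called higher (3 adjusted over the list alone). Photosynthesis genes were higher in 10 of 16 (11 adjusted over the list alone; camera adjusted p = 0.000238, and adjusted p = 0.272 with an estimated correlation), and phenylpropanoid genes in 13 of 22 (13 adjusted over the list alone; camera adjusted p = 6.01e-06, and adjusted p = 0.246 with an estimated correlation), with 4CL2 (AT3G21240) at 0.74 ± 0.12, 4CL1 at 0.67 ± 0.095 and OMT1 (AT5G54160) at 0.49 ± 0.072. Of the phenylpropanoid genes 2 were called lower (2 adjusted over the list alone), a count of 1 without ref5-1 replicate 2, ref5-1 replicate 3, ref2-1 replicate 1 or ref2-1 replicate 2. Xylem and secondary wall markers were higher in 7 of 11 (8 adjusted over the list alone; camera adjusted p = 0.000129, and adjusted p = 0.32 with an estimated correlation), a count of 4 without ref2-1 replicate 2. Of these CESA7 (AT5G17420) and XCP1 (AT4G35350) were higher by 1.88-fold and 2.12-fold, and the flowering genes FT (AT1G65480) and SOC1 by 1.90-fold and 1.81-fold. Of the root markers 1 of 2 was called higher (2 adjusted over the list alone; camera adjusted p = 0.0281, and adjusted p = 0.264 with an estimated correlation). That count was 2 without ref5-1 replicate 2. The list p was 0.072 without ref5-1 replicate 3. The test called 4258 genes, 2066 higher and 2192 lower in ref5-1, and a fit to the 6 compared libraries alone called 2816.

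Shared changes were counted next. Of the calls against wild type, 800 had the same direction in ref5-1 and ref2-1, 400 higher and 400 lower, and 87 had opposite directions. Independent lists would share 217.7. KFB39, KFB50, MYB4, PR2, AKR4C9 and CYP81F3 were called higher in both, and HCT and LHY lower in both. In ref5-1 HCT was at −0.36 ± 0.076 and LHY at −0.40 ± 0.085, and a fit to the 6 compared libraries alone called neither. Both comparisons use the same wild type libraries. In 20 simulated sets all libraries, wild type included, were redrawn with ref5-1 and ref2-1 at the wild type means. These sets gave 0 shared calls, with at most 1 call per comparison. They cannot show how shared controls add shared calls where many genes are called. The mean correlation of log2 fold changes across genes in these sets was 0.504, beside the observed 0.445. Their mean covariance was 0.0354 beside the observed 0.172, a difference of 0.137. The overlap was 503 in fits to the compared libraries alone, 375 without wild type replicate 1 and 313 without wild type replicate 2, and 3 wild type libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Where no library was shared, ref5-1 against wild type and ref2-1 med5 against med5 had 528 calls in the same direction (143.0 for independent lists) and 63 in opposite directions. Likewise ref2-1 against wild type and ref5-1 med5 against med5 had 868 (261.1) and 157.

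In med5 the transcripts of KFB39 and MYB4 were lower than in wild type, and phenylpropanoid genes were higher. KFB39 fell 6.29-fold, from 11.9 ± 0.514 to 1.91 ± 0.264 CPM (adjusted p = 2.26e-08), the chaperone-like J-protein gene AT3G13310 fell 5.06-fold to 2.69 ± 0.350 CPM, the cupin-family gene AT2G43120 fell 5.31-fold, and MYB4 fell 1.60-fold to 14.1 ± 0.754 CPM (adjusted p = 0.00142). Of the 5 F-box genes 1 was called lower (2 adjusted over the list alone; camera adjusted p = 0.00385, and adjusted p = 0.529 with an estimated correlation), a count of 2 without med5 replicate 2 and, as above, not independent evidence. In the phenylpropanoid list 6 of 22 genes rose (12 adjusted over the list alone; camera adjusted p = 4.39e-10, and adjusted p = 0.0896 with an estimated correlation), with 4CL2 at 0.99 ± 0.11, 4CL1 at 0.87 ± 0.095 and CCoAOMT1 (AT4G34050) at 0.49 ± 0.073. In this list 1 was called lower (1 adjusted over the list alone). The flavonoid and anthocyanin list leaned down (median log2 fold change −0.438, camera adjusted p = 0.000647, and adjusted p = 0.749 with an estimated correlation). Of its 22 genes edgeR called 0, also over the list alone, and DESeq2 called 1 lower, with 9 at an unadjusted p under 0.05. The list p was 0.432 without wild type replicate 3. PAL4 (AT3G10340), an isoform of the entry enzyme, rose 3.44-fold, from 10.8 ± 2.13 to 37.0 ± 14.1 CPM, though a fit to the 6 compared libraries alone gave it adjusted p = 0.112. ESM1, which shifts glucosinolate breakdown, rose 3.17-fold to 1071 ± 182 CPM, and the ERF-family gene AT1G64380 rose 3.54-fold. MRD1 fell from 28.7 ± 0.871 CPM to 1.02 ± 0.798 CPM. Floral and flowering genes leaned up as a group (median log2 fold change 0.836; camera adjusted p = 1.98e-05, and adjusted p = 0.0896 with an estimated correlation), with 10 higher and 1 lower of 11 when adjusted over the list alone. Over all genes 0 of these 11 were called by edgeR and 0 by DESeq2, and 11 had an unadjusted p under 0.05. The salicylate list leaned up as well (median log2 fold change 1; camera adjusted p = 4.12e-07, and adjusted p = 0.529 with an estimated correlation), with 1 of 17 genes called by edgeR, 6 adjusted over the list alone, 7 by DESeq2 and 7 at an unadjusted p under 0.05. The edgeR count was 0 without wild type replicate 1, wild type replicate 2, wild type replicate 3 or med5 replicate 3 and 2 without med5 replicate 2. PR1 was at 42.8 ± 57.1 CPM, where the 3 libraries spread more than their mean.

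The comparison called 155 genes, 67 higher and 88 lower, which is 43.2% higher. DESeq2 called 500, of which 284 were higher and 216 lower, or 56.6% higher. Single libraries moved the count: it was 52 without wild type replicate 1, 78 without wild type replicate 2, 76 without med5 replicate 1 and 66 without med5 replicate 3. Without the third libraries of wild type and med5 it was 69.

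In the ref5-1 background KFB39, KFB50 and cold response genes were lower with the med5 alleles, and phenylpropanoid genes were higher. KFB39 fell 27.4-fold, from 65.1 ± 11 to 2.34 ± 0.380 CPM (adjusted p = 8.43e-13). AT3G13310 fell 27.7-fold to 2.33 ± 0.287 CPM, AT2G43120 9.98-fold, KFB50 3.1-fold to 39.8 ± 2.59 CPM and MYB4 2.35-fold to 14.98 ± 0.521 CPM. The F-box list had 2 of 5 genes lower (2 adjusted over the list alone; camera adjusted p = 0.000231, and adjusted p = 0.227 with an estimated correlation), again not independent evidence. Of 22 phenylpropanoid genes 14 rose (14 adjusted over the list alone; camera adjusted p = 1.09e-08, and adjusted p = 0.2 with an estimated correlation), with 4CL2 at 1.43 ± 0.11, 4CL1 at 1.04 ± 0.095 and CCoAOMT1 at 0.70 ± 0.073. Another 2 were called lower (2 adjusted over the list alone), a count of 1 without ref5-1 replicate 1, ref5-1 replicate 2, ref5-1 replicate 3, ref5-1 med5 replicate 2 or ref5-1 med5 replicate 3. Cold and abscisic acid genes fell in 7 of 11 cases (10 adjusted over the list alone; camera adjusted p = 7.03e-09, and adjusted p = 0.2 with an estimated correlation), with KIN1 at −3.14 ± 0.52, COR15B at −2.73 ± 0.39, COR15A (AT2G42540) at −2.60 ± 0.40 and LTI30 at −2.23 ± 0.33. Flavonoid and anthocyanin genes fell in 12 of 22 (16 adjusted over the list alone; camera adjusted p = 5.1e-10, and adjusted p = 0.295 with an estimated correlation), a count of 6 without ref5-1 med5 replicate 2, and included UGT79B1 (AT5G54060) at −2.32 ± 0.44, GSTF12 (AT5G17220) at −2.0 ± 0.33, 5MAT (AT3G29590) at −1.97 ± 0.31 and TT8 (AT4G09820) at −1.37 ± 0.21. PR1 rose from 0.662 ± 0.0999 CPM to 98.9 ± 58.8 CPM (adjusted p = 0.00492). The salicylate list moved up as a group (camera adjusted p = 5.3e-07, and adjusted p = 0.295 with an estimated correlation). Of its 17 genes 7 were called higher (12 adjusted over the list alone), a count of 2 to 12 with a library left out. The detoxification genes GSTU19 (AT1G78380) and OPR1 (AT1G76680) rose 1.34-fold and 2.01-fold, LHY rose 1.62-fold, and TMM, a receptor of the stomatal lineage, fell 1.92-fold. Auxin genes moved both ways, GH3.5 at 0.70 ± 0.14, GH3.6 at 0.61 ± 0.12, IAA1 (AT4G14560) at −0.59 ± 0.12 and IAA5 at −0.89 ± 0.15, but did not pass as a list (camera adjusted p = 0.116; 0.0118 without ref5-1 replicate 1 and 0.0164 without ref5-1 med5 replicate 3). Markers of the stomatal lineage moved down, 2 of 5 genes called lower (2 adjusted over the list alone, camera adjusted p = 0.0056, and adjusted p = 0.227 with an estimated correlation).

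Between these genotypes 2149 genes were called, 1211 higher and 938 lower. The count was 1263 without ref5-1 replicate 1, 897 without ref5-1 med5 replicate 2 and 1159 without ref5-1 med5 replicate 3, and 1166 in a fit to the 6 compared libraries alone. The library ref5-1 med5 replicate 1 had 25.3% of reads with several alignments, against 3.71% to 8.91% elsewhere, and the count without it was 2216.

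In the ref2-1 background the med5 alleles again lowered KFB39, by 20.6-fold, from 65.4 ± 3.02 to 3.17 ± 0.787 CPM (adjusted p = 2.16e-12). AT3G13310 fell 26.8-fold, KFB50 2.49-fold and MYB4 2.80-fold. KFB39 and KFB50 were the 2 of 5 F-box genes called (2 adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.51 with an estimated correlation), which is not independent evidence, and the list p was 0.0563 without ref2-1 replicate 2. The phenylpropanoid list rose in 12 of 22 genes (14 adjusted over the list alone), fell in 3 and passed as a group (camera adjusted p = 3.7e-08, and adjusted p = 0.136 with an estimated correlation). PAL4 rose 8.91-fold, from 3.498 ± 1.23 to 31.4 ± 4.22 CPM (adjusted p = 1.82e-05), with 4CL2 at 1.81 ± 0.11, 4CL1 at 1.43 ± 0.096 and CCoAOMT1 at 0.77 ± 0.073. MYB43 (AT5G16600), a gene of secondary wall regulation, rose 3.82-fold. Xylem and secondary wall markers leaned up beside the phenylpropanoid genes (median log2 fold change 0.444; camera adjusted p = 0.0043, and adjusted p = 0.528 with an estimated correlation), and the list p was 0.0503 without ref2-1 med5 replicate 3. Of these 11 genes edgeR called 1, 4 adjusted over the list alone, and DESeq2 2, with 5 at an unadjusted p under 0.05. The edgeR test called 0 without ref2-1 replicate 2 or 3 or any of the 3 ref2-1 med5 libraries. Flavonoid and anthocyanin genes fell, 10 of 22 (17 adjusted over the list alone; camera adjusted p = 1.07e-10, and adjusted p = 0.51 with an estimated correlation), with TT7 (AT5G07990) at −2.37 ± 0.46, 5MAT at −1.97 ± 0.33, LDOX (AT4G22880) at −1.88 ± 0.35 and GSTF12 at −1.81 ± 0.33. The early light-induced genes ELIP1 (AT3G22840) and ELIP2 (AT4G14690) fell 8.44-fold and 7.03-fold, and QQS fell from 43.9 ± 8.83 CPM to 4.71 ± 1.05 CPM. Flowering and floral organ genes rose in 8 of 11 (9 adjusted over the list alone; camera adjusted p = 8.48e-08, and adjusted p = 0.0507 with an estimated correlation), with FT at 6.11 ± 0.635 CPM against 2.85 ± 0.707 CPM and SEP3 at 1.90 ± 0.36, AP3 (AT3G54340) at 1.90 ± 0.41 and AP1 (AT1G69120) at 1.66 ± 0.34. The auxin conjugase genes GH3.5 at 1.44 ± 0.16 and GH3.6 at 0.87 ± 0.12 were called higher, while the auxin-response list did not pass as a group (camera adjusted p = 0.0709; 0.0165 without ref2-1 replicate 3). It had 5 of 19 genes higher (7 adjusted over the list alone), a count of 3 without ref2-1 replicate 1. Another 2 were lower (3 adjusted over the list alone), a count of 1 without ref2-1 replicate 1, ref2-1 replicate 3 or ref2-1 med5 replicate 2 and 0 without ref2-1 med5 replicate 3. PR5 fell 5.26-fold, and the asparaginase ASPGB1 (AT3G16150) rose 7.13-fold to 11.9 ± 3.25 CPM. The salicylate list passed camera (adjusted p = 0.0136, and 0.141 without ref2-1 med5 replicate 1), with 1 gene called lower and 0 higher. A fit to the 6 compared libraries alone did not call TT7 and PR5.

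The number of calls was 1773, 925 higher and 848 lower. It was 937 without ref2-1 replicate 1, 1076 without ref2-1 replicate 3, 930 without ref2-1 med5 replicate 1 and 762 without ref2-1 med5 replicate 2. Across backgrounds, 454 genes had the same direction in both triple mutants against their parents, beside 96.28 for independent lists, and 26 had opposite directions. Over all tested genes the log2 fold changes of these comparisons correlated at only 0.153. Those of med5 against wild type correlated at 0.574 with the ref5-1 background and at 0.165 with the ref2-1 background. Of the 155 genes called in med5 against wild type, 93 were called in the same direction in the ref5-1 background, and 69 in the ref2-1 background with 3 in the opposite direction.

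**Figure D3:**
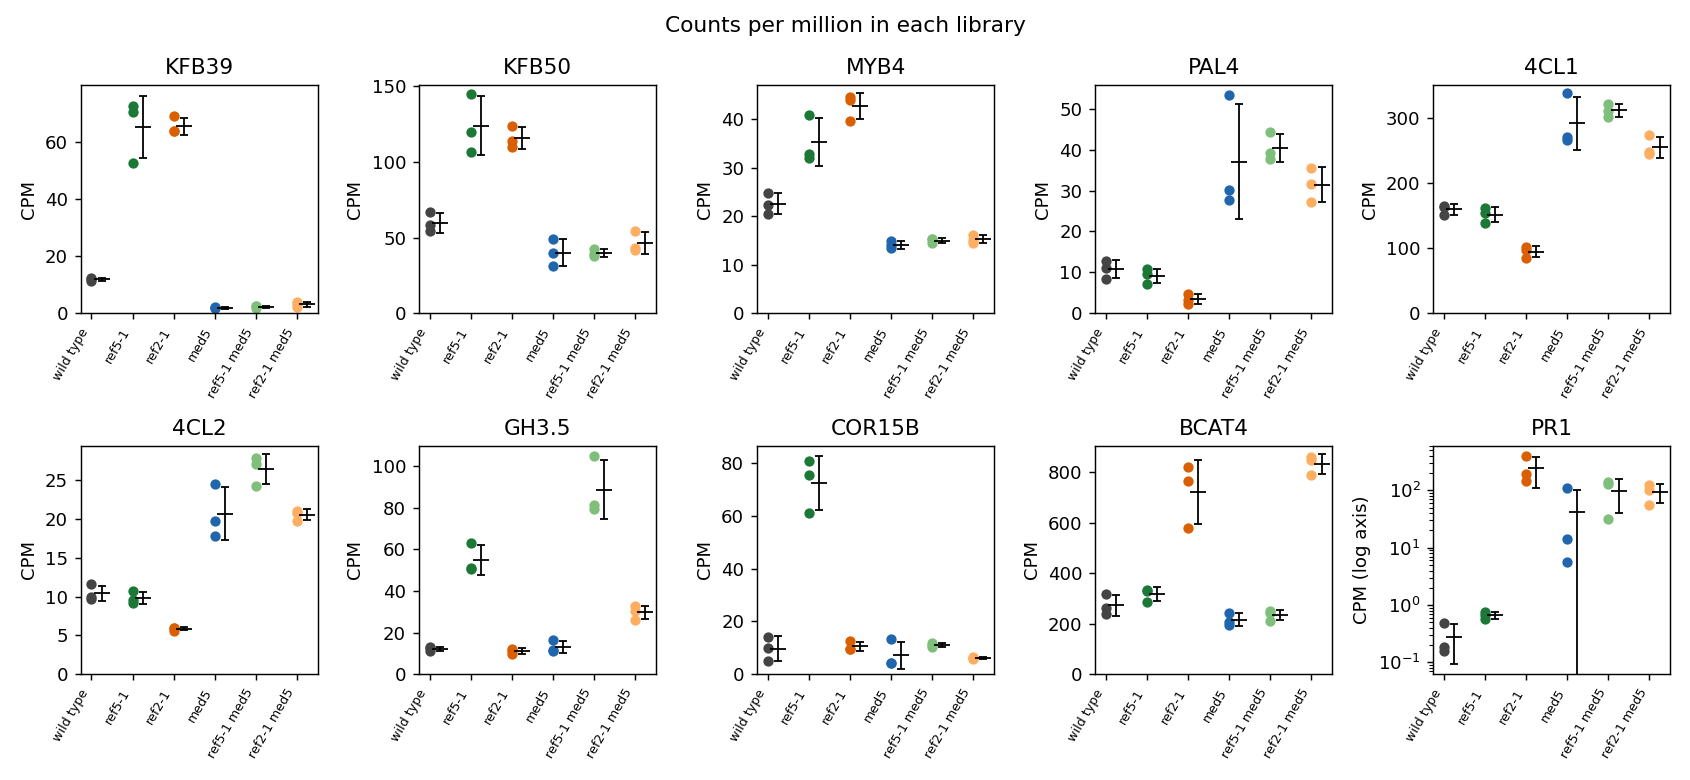
Levels of 10 genes in CPM for each library (points) by genotype, with bars at the mean ± SD of 3 libraries. PR1 is drawn on a log axis, where the bar of med5 runs below the axis because its SD exceeds its mean, and KFB39 stands at 65.1 CPM in ref5-1, 65.4 CPM in ref2-1 and 1.91 CPM in med5.

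Without MED5 the ref5-1 allele still raised auxin genes. In ref5-1 med5 against med5, 13 of 19 were called higher (13 adjusted over the list alone; camera adjusted p = 9.36e-15, with adjusted p = 0.00767 under an estimated correlation), with GH3.3 at 2.98 ± 0.19, GH3.5 at 2.76 ± 0.16, GH3.6 at 1.68 ± 0.12 and IAA19 at 1.41 ± 0.14. GH3.3 reached 80.0 ± 10.8 CPM from 10.2 ± 1.90 CPM (adjusted p = 8.67e-08). Detoxification genes rose, 8 of 9 (9 adjusted over the list alone; camera adjusted p = 6.27e-08, and adjusted p = 0.106 with an estimated correlation), a count of 4 without med5 replicate 1, 5 without med5 replicate 3 and 5 without ref5-1 med5 replicate 3, with AKR4C9 at 3.02 ± 0.32, OPR1 at 1.01 ± 0.21 and GSTU19 at 0.51 ± 0.07. In the phenylpropanoid list 6 of 22 were called higher (6 adjusted over the list alone; camera adjusted p = 0.0124, and adjusted p = 0.463 with an estimated correlation). That count was 1 without med5 replicate 1 or med5 replicate 3 and 2 without ref5-1 med5 replicate 2 or ref5-1 med5 replicate 3. The sulfate genes APS4 (AT5G43780) and APR3 rose 2.06-fold and 1.74-fold. Their list did not pass as a group (camera adjusted p = 0.08), with 3 genes called higher and 1 lower. Of 17 salicylate genes 4 were called higher and the list passed as a group (camera adjusted p = 7.95e-05), a count of 0 to 7 with a library left out. In this comparison only the auxin-response list passed with an estimated correlation. AZI1 (AT4G12470), a gene of systemic immunity, reached 14.6 ± 3.38 CPM from 0.482 ± 0.433 CPM, AT4G15160 26.3 ± 4.47 CPM from 0.417 ± 0.325 CPM, and BGLU23 410.0 ± 36.3 CPM from 79.8 ± 25.8 CPM. FSD1 fell from 453 ± 93.4 CPM to 53.0 ± 13.7 CPM (adjusted p = 8.71e-05). The cytokinin response regulator genes ARR15 at −2.02 ± 0.19, ARR6 (AT5G62920) at −1.37 ± 0.16 and RR16 (AT2G40670) at −1.24 ± 0.17 were called lower, and no list of this family was fixed or tested. Stomatal lineage markers moved down, opposite to the auxin and detoxification genes, 3 of 5 genes called lower (5 adjusted over the list alone, camera adjusted p = 0.000121, and adjusted p = 0.0924 with an estimated correlation). That count was 1 without med5 replicate 1 or ref5-1 med5 replicate 2. Root markers moved up, 1 of 2 measured genes called higher (2 adjusted over the list alone, camera adjusted p = 0.00354, and adjusted p = 0.106 with an estimated correlation). That count was 2 without med5 replicate 2. The stomatal gene TMM fell 2.11-fold, and the floral genes AG (AT4G18960) and AP3 fell 5.91-fold and 3.75-fold. Of 11 flowering and floral organ genes 4 were called lower and 1 higher (camera adjusted p = 0.00927). With a library left out these counts were 2 to 4 and 0 to 1. KFB39 was at 1.91 ± 0.264 CPM in med5 and 2.34 ± 0.380 CPM in ref5-1 med5, where the change was not called. Calls numbered 2077, 1241 higher and 836 lower, with 1078 without med5 replicate 1 and 1274 without ref5-1 med5 replicate 2.

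The ref2-1 allele raised aliphatic glucosinolate genes without MED5 as well. Between ref2-1 med5 and med5, 20 of 26 were called higher (20 adjusted over the list alone; camera adjusted p = 3.27e-15, and adjusted p = 0.152 with an estimated correlation), with BCAT4 at 1.95 ± 0.13, AOP2 at 1.25 ± 0.099 and BAT5 at 1.13 ± 0.084, while 1 was called lower (1 adjusted over the list alone). The adenylyl sulfate reductases APR3 and APR1 rose 2.72-fold and 2.04-fold, and the transporters SULTR4;2 and SULTR2;1 1.64-fold and 1.51-fold. Detoxification genes rose, 7 of 9 (9 adjusted over the list alone; camera adjusted p = 2.45e-08, and adjusted p = 0.152 with an estimated correlation), with CYP81D11 (AT3G28740) at 4.37 ± 0.72, AKR4C9 at 3.07 ± 0.32 and OPR1 at 1.47 ± 0.21. PR2 rose 8.74-fold and CBP60G 6.96-fold in this test, and fits to the 6 compared libraries alone did not call these genes. Their salicylate list passed as a group (camera adjusted p = 1.88e-05), with 6 of 17 genes called higher, a count of 2 to 7 with a library left out. No list of this comparison passed with an estimated correlation. FLC reached 3.096 ± 0.333 CPM from 0.875 ± 0.205 CPM. Glucosinolate breakdown genes fell in 3 of 6 (3 adjusted over the list alone; camera adjusted p = 0.0226, and adjusted p = 0.359 with an estimated correlation): ESM1 at −1.65 ± 0.17, TGG2 (AT5G25980) at −1.44 ± 0.29 and TGG1 at −1.09 ± 0.21. Auxin genes IAA29 and IAA5 fell 3.0-fold and 2.05-fold, while GH3.5 rose 2.26-fold, and their list did not pass as a group (camera adjusted p = 0.399). In the phenylpropanoid list 5 of 22 were called lower (5 adjusted over the list alone; camera adjusted p = 0.0232, and adjusted p = 0.435 with an estimated correlation). That count was 3 without med5 replicate 2, ref2-1 med5 replicate 1 or ref2-1 med5 replicate 3 and 1 without med5 replicate 3 or ref2-1 med5 replicate 2. The list p was 0.156 without med5 replicate 2 and 0.0759 without ref2-1 med5 replicate 2. HCT fell 1.35-fold to 172 ± 9.09 CPM, and FAMA 1.36-fold. Xylem and secondary wall markers moved down, 3 of 11 genes called lower (3 adjusted over the list alone, camera adjusted p = 0.00411, and adjusted p = 0.435 with an estimated correlation). That count was 0 without med5 replicate 1, ref2-1 med5 replicate 1 or ref2-1 med5 replicate 2 and 1 without med5 replicate 2. Stomatal lineage markers moved as well, 2 of 5 genes called lower (2 adjusted over the list alone; camera adjusted p = 0.0448, and adjusted p = 0.359 with an estimated correlation). That count was 1 without med5 replicate 1, ref2-1 med5 replicate 1 or ref2-1 med5 replicate 3. The list p was 0.064 without med5 replicate 1, 0.0625 without med5 replicate 2 and 0.215 without ref2-1 med5 replicate 3. The anthocyanin regulator TT8 fell 2.18-fold. Its flavonoid and anthocyanin list passed as a group (camera adjusted p = 0.000981), with 5 of 22 genes called lower and 0 higher. The lower count was 1 to 3 with a library left out. Calls numbered 3238, 1741 higher and 1497 lower, with 1578 without med5 replicate 1, 1800 without ref2-1 med5 replicate 1 and 1937 without ref2-1 med5 replicate 2.

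The interactions asked whether an allele's effect differed with MED5 lost. For ref5-1, KFB39 had an interaction of −2.12 ± 0.25 on the log2 scale (adjusted p = 0.000327), with a rise of 5.45-fold in the presence of MED5 and no call without it. AT3G13310 had −2.45 ± 0.20, the cold-induced membrane protein gene COR413IM1 (AT1G29395) −2.40 ± 0.32, the light-response gene LZF1 (AT1G78600) −1.27 ± 0.15, the protein kinase gene AT2G30740 1.43 ± 0.16 and the clock gene LHY 0.78 ± 0.12. COR413IM1 was at 33.9 ± 4.46 CPM in ref5-1 and 7.84 ± 1.07 CPM in ref5-1 med5. For ref2-1, KFB39 had −1.71 ± 0.24 (adjusted p = 0.00245), with a rise of 5.47-fold in the presence of MED5 and of 1.67-fold (adjusted p = 0.0165) without it, which was not called without med5 replicate 1 (adjusted p = 0.0685), med5 replicate 2 (0.0602), ref2-1 med5 replicate 1 (0.0894) or ref2-1 med5 replicate 2 (0.0542). Further genes were AT3G13310 −2.40 ± 0.19, MYB4 −0.81 ± 0.14, ESM1 −2.04 ± 0.23, QQS −3.44 ± 0.37 and, in the other direction, GH3.5 1.33 ± 0.22 and ASPGB1 2.28 ± 0.39. Among lists, 10 passed camera with ref5-1 and 8 with ref2-1. None passed with an estimated correlation, and fry called 0 lists in either interaction. With ref5-1 they included detoxification (camera adjusted p = 8e-05), aliphatic glucosinolate (0.000116), F-box (0.00035, not independent evidence) and flowering and floral organ genes (0.00149). In these lists edgeR called 0 genes apart from 1 F-box gene. The cold and abscisic acid genes had a median interaction of −1.76 with ref5-1 (camera adjusted p = 2.19e-10, and adjusted p = 0.238 with an estimated correlation). Of these 11 genes 0 were called by edgeR over all genes (1 without wild type replicate 3) and 3 by DESeq2, 6 were called when adjusted over the list alone, and 8 had an unadjusted p under 0.05. The flavonoid list had medians of −0.48 with ref5-1 (camera adjusted p = 1.74e-06, and adjusted p = 0.369 with an estimated correlation) and −0.525 with ref2-1 (camera adjusted p = 0.000127, and adjusted p = 0.676 with an estimated correlation). Of its 22 genes edgeR called 0 in either interaction, also over the list alone, and DESeq2 0, with 5 and 6 at an unadjusted p under 0.05. The phenylpropanoid list did not pass with ref5-1 (camera adjusted p = 0.0686; 0.00945 without wild type replicate 1, 0.0273 without wild type replicate 2 and 0.0067 without med5 replicate 2). With ref2-1 its median was 0.226 (camera adjusted p = 0.0453, and adjusted p = 0.676 with an estimated correlation), and the list p was 0.352 without wild type replicate 3, 0.179 without ref2-1 replicate 2, 0.0701 without ref2-1 replicate 3, 0.102 without med5 replicate 1, 0.0624 without med5 replicate 3, 0.0937 without ref2-1 med5 replicate 1 and 0.123 without ref2-1 med5 replicate 3. Its calls with ref2-1 went both ways. By edgeR 2 were higher (0 to 5 with a library left out) and 3 lower (1 to 3), and by DESeq2 5 and 3. The salicylate list had a median of −1.88 with ref2-1 (camera adjusted p = 5.79e-08, and adjusted p = 0.6 with an estimated correlation), where 1 of 17 genes was called by edgeR, 5 adjusted over the list alone, 6 by DESeq2 and 8 at an unadjusted p under 0.05. The edgeR count was 0 without wild type replicate 1, wild type replicate 2, ref2-1 replicate 1, ref2-1 replicate 2, ref2-1 replicate 3, med5 replicate 3, ref2-1 med5 replicate 1 or ref2-1 med5 replicate 2 and 5 without med5 replicate 2. For the sulfate list with ref5-1 the median was −0.155, the mean 0.0132 and the test direction down (camera adjusted p = 0.0193, and adjusted p = 0.462 with an estimated correlation), and the list p rose to 0.18 without wild type replicate 1, 0.0552 without wild type replicate 2, 0.136 without med5 replicate 3, 0.0597 without ref5-1 med5 replicate 1 and 0.118 without ref5-1 med5 replicate 2.

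Of the 1735 genes called in ref5-1 against wild type, 822 (47.4%) were called in the same direction without MED5, beside 93.62 for independent lists, and 3 in the opposite direction; 1591 (91.7%) had the same sign. The interaction with ref5-1 called 18 genes. In 14 of them the call in ref5-1 against wild type and the interaction had opposite signs. Of the 4915 genes called in ref2-1, 1715 (34.9%) were called in the same direction without MED5, beside 402.7, and 22 in the opposite direction; 4353 (88.6%) had the same sign. The interaction with ref2-1 called 149 genes. In 117 of them the call in ref2-1 against wild type and the interaction had opposite signs. Both counts compare signs and not sizes, so they include effects that turn without MED5, as LHY at −0.40 in ref5-1 with an interaction of 0.78. The effect against wild type and the interaction use the same wild type and ref libraries, so opposite signs are partly built in. The counts of 18 and 149 include AT3G01345, AT5G35935 and AT3G55240, where wild type stood apart from every mutant genotype, so that their interactions restate that difference. With libraries left out the kept share for ref5-1 ran from 34.2% (without med5 replicate 1) to 62.6%. It was 55.4% without wild type replicate 1 and 62.6% without wild type replicate 2, where fewer calls, 506 and 448, were kept of fewer in all. Fits to the compared libraries alone kept 446, or 42.2%. For ref2-1 it was 19.7%, or 951 genes, without med5 replicate 1 and 23.5%, or 1131, without ref2-1 med5 replicate 1. DESeq2 called 126 genes in the interaction with ref5-1, 47 higher and 79 lower, and a fit to the compared libraries alone 10. For ref2-1 DESeq2 called 592, 258 higher and 334 lower (43.6% higher, against 61.1% in edgeR). With the replicate number as a block that count was 297, and without the third libraries of wild type and med5 65. The interaction counts leaned on single libraries: 10 without wild type replicate 1, 33 without wild type replicate 3, 10 without ref5-1 replicate 3, 11 without ref5-1 med5 replicate 1 and 10 without ref5-1 med5 replicate 3 for ref5-1. For ref2-1 they were 40 without wild type replicate 1, 66 without wild type replicate 2, 251 without wild type replicate 3, 77 without ref2-1 replicate 1, 64 without med5 replicate 1, 475 without med5 replicate 2, 44 without med5 replicate 3, 71 without ref2-1 med5 replicate 1 and 38 without ref2-1 med5 replicate 2.

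**Figure D4:**
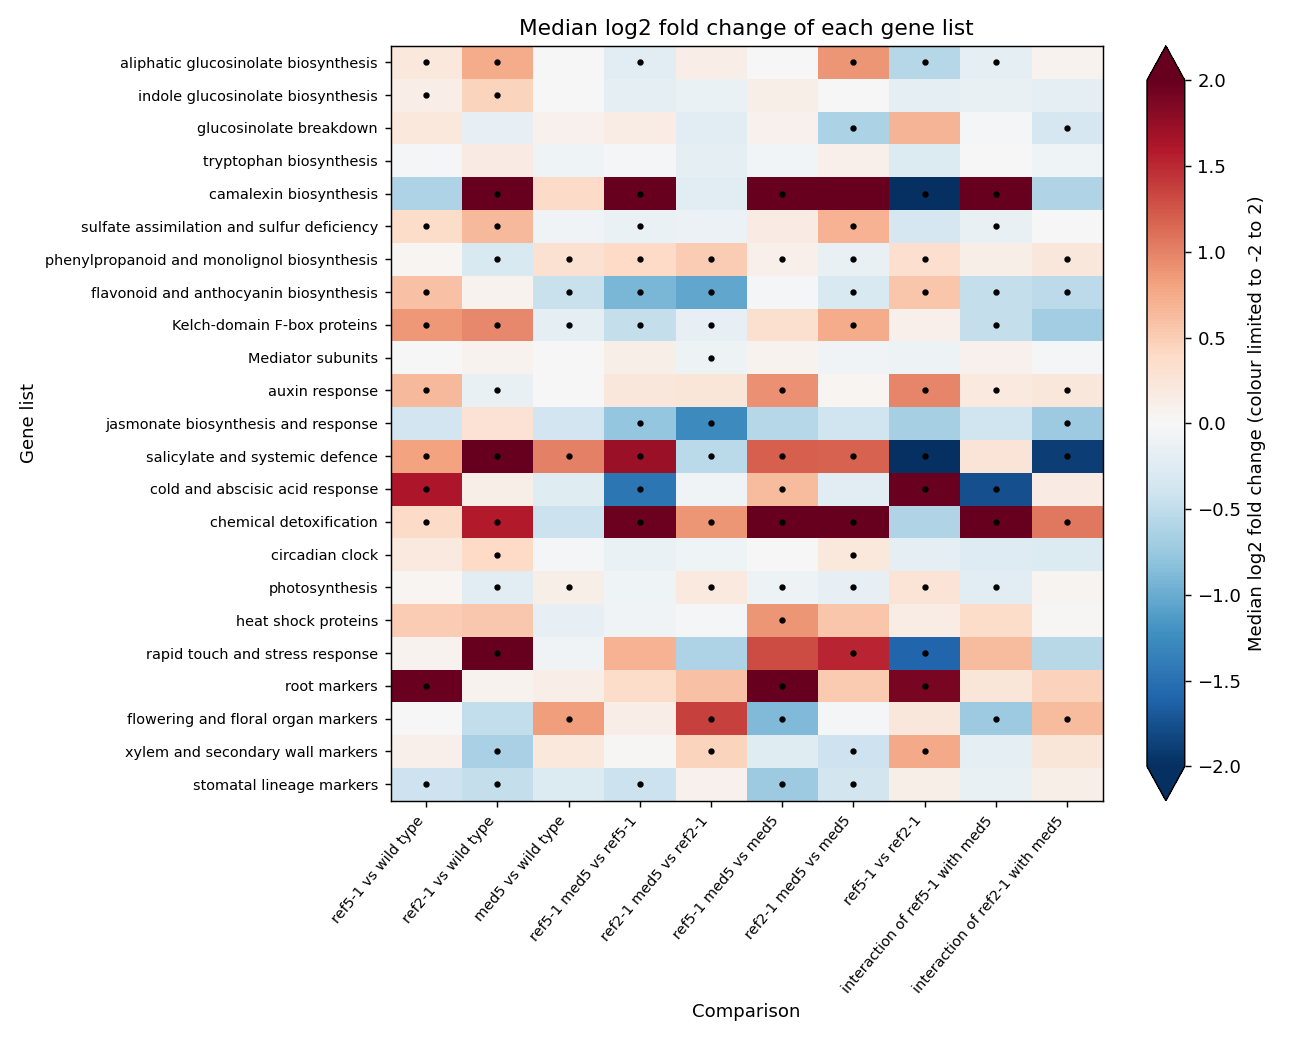
Median log2 fold change (colour, limited to −2 to 2) of 23 gene lists (vertical axis) in 10 comparisons (horizontal axis), with a dot where camera gave an adjusted p under 0.05. The salicylate list in ref2-1 against wild type has a median of 3.69, and the cold list in ref5-1 against wild type 1.61.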

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

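The tests of the first 3 patterns below were put to this use after the results were seen. Of the runs they draw on, thinning was also added after the data were seen. The fits to the compared libraries alone and the counts of calls with single libraries left out had been fixed before the data were examined. The counts of other groupings were planned. A pair of genes separated wild type from every mutant genotype. AT3G01345 had 7873 to 9280 counts in the wild type libraries and 2 to 16 in the mutant libraries, while the pseudogene AT5G35935 had 10 to 16 counts in wild type and 287 to 582 in the mutants. A swap between a wild type and a mutant library is argued against by the highest mutant level of AT3G01345, 0.631 CPM, since such a library would bring the wild type level. That level is part of the pattern itself and no separate test, and it says nothing on swaps among mutant libraries. A variant carried by the wild type stock is a candidate explanation. In edgeR 0 of 10 tests between mutant genotypes called these genes, with 3 at an unadjusted p under 0.05 and 1 called by DESeq2. These tests cannot decide, since AT3G01345 was near the floor in every mutant library and both genes were picked for setting wild type apart from every mutant. The neighbours AT3G01340 and AT5G35930 were not called against wild type, while AT3G01350 was lower in ref2-1 (−0.47, adjusted p = 0.0116). A response to the mutations themselves had 6 calls in the 6 tests of ref5-1, ref2-1 and med5 against wild type. It cannot be told apart from a stock variant, because every mutant is set against the same wild type libraries.

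The med5 alleles called 155 genes against wild type and 2149 and 1773 in the ref5-1 and ref2-1 backgrounds. With 1 library left out these counts reached at most 184 (without med5 replicate 2) against wild type, and fell to no less than 897 (without ref5-1 med5 replicate 2) and 762 (without ref2-1 med5 replicate 2). The gap was smaller by other measures. In the same order DESeq2 called 500, 2512 and 2102 genes, and 2442, 5316 and 4927 had an unadjusted p under 0.05 in edgeR. The SD of log2 fold changes was 0.435, 0.571 and 0.449, so the size of the gap depends on the threshold and method. Library depth is argued against by 1640 calls in the ref2-1 background with all libraries thinned to the lowest depth, beside 156 against wild type, and the spread shared between genotypes by 1166 calls in the ref5-1 background with the compared libraries alone, beside 148. An effect of med5 that differs by background may account for part of it, since 119 of the 1701 genes called in the ref2-1 background and not against wild type were also called in the interaction, and 12 of 2056 in the ref5-1 background. It stays open, because the interaction called some and not most of these genes, and its count moved with single libraries, for ref2-1 from 38 without ref2-1 med5 replicate 2 to 475 without med5 replicate 2.

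The share of reads with several alignments was 25.3% in ref5-1 med5 replicate 1, while the wild type libraries, read as controls, reached 5.77%. Transcripts of the organelles may be part of the reason, since its chloroplast share of gene counts, 0.263%, was 3.07 times that of the next library. Without this library ref5-1 med5 against ref5-1 had 2216 calls, beside 2149 with it, and 1753 of them were shared in the same direction. The calls went from 1211 higher and 938 lower to 1382 higher and 834 lower. These counts cannot decide whether a shift of its gene counts lies behind some calls, since a library that stands apart can both add and cost calls. No biological explanation was tested.

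Other libraries above the highest wild type share were ref5-1 replicates 1 and 3 at 7.14% and 6.01%, ref2-1 replicates 1 and 2 at 6.94% and 8.91%, med5 replicate 2 at 6.43%, ref5-1 med5 replicate 3 at 6.02%, and ref2-1 med5 replicates 1 and 2 at 7.13% and 6.26%.

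The interaction test for ref5-1 called 18 genes, a count that moved with single libraries as given above. Of these, 15 were named by the rule and run with each library left out, and AT1G66830, AT2G39920 and AT2G47880 were not. In AT5G35935 (−5.22), AT3G01345 (9.30) and AT3G55240 (1.09) wild type stood apart from all mutants, whose levels were alike, so these values restate that difference and are not read as a response that needs MED5. Among the other named genes, those called in every set run were AT3G13310 at −2.45, COR413IM1 at −2.40, KFB39 at −2.12, LZF1 at −1.27, LHY at 0.78 and AT2G30740 at 1.43. The named genes that lost the call are given with the highest adjusted p when 1 library was left out: AT5G10410 −1.50 (adjusted p = 0.138 without wild type replicate 1), J11 (AT4G36040) −1.3 (adjusted p = 0.0996 without wild type replicate 1), PPCK1 (AT1G08650) −1.05 (adjusted p = 0.157 without wild type replicate 1), PIP2;5 (AT3G54820) −0.83 (adjusted p = 0.109 without ref5-1 med5 replicate 3), AT4G36850 1.1 (adjusted p = 0.157 without wild type replicate 1) and AT3G62460 1.23 (adjusted p = 0.157 without wild type replicate 1). For ref2-1 the test called 149 genes, with the same limit, of which 27 were named and run with each library left out. AT5G35935 (−4.78) and AT3G01345 (8.78) again restate the difference of wild type. Among the other named genes, those called in every set run were QQS at −3.44, AT3G13310 at −2.40, ESM1 at −2.04, KFB39 at −1.71, MYB4 at −0.81, GH3.5 at 1.33, AT5G05960 at 1.51, ASPGB1 at 2.28, MRD1 at 3.32 and MLP34 (AT1G70850) at 4.56, where the med5 level of MLP34 was 0.127 ± 0.126 CPM. MRD1 was far higher in wild type than in med5 and ref5-1, as given above, so its interaction may in part restate that difference. The named genes that lost the call were PR1 −8.61 (adjusted p = 0.147 without wild type replicate 1), HO3 (AT1G69720) −3.13 (adjusted p = 0.13 without wild type replicate 1), ELIP1 −2.70 (adjusted p = 0.104 without ref2-1 med5 replicate 2), AT2G39920 −2.29 (adjusted p = 0.0792 without wild type replicate 1), AT3G22060 −1.63 (adjusted p = 0.0759 without wild type replicate 1), UGT84A2 (AT3G21560) −0.97 (adjusted p = 0.0922 without ref2-1 med5 replicate 2), ALDH2C4 −0.61 (adjusted p = 0.103 without wild type replicate 1), PAI1 (AT1G07780) 0.60 (adjusted p = 0.139 without wild type replicate 1), LHY 0.61 (adjusted p = 0.0781 without wild type replicate 1), 4CL2 0.82 (adjusted p = 0.0605 without ref2-1 med5 replicate 2), THI2.2 (AT5G36910) 1.68 (adjusted p = 0.0783 without wild type replicate 1), AT2G05540 1.85 (adjusted p = 0.119 without med5 replicate 3), AT4G27570 1.85 (adjusted p = 0.0551 without ref2-1 med5 replicate 2), AT4G11211 1.87 (adjusted p = 0.134 without ref2-1 med5 replicate 2) and SIS (AT5G02020) 1.90 (adjusted p = 0.125 without ref2-1 med5 replicate 2).

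Other groupings of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, called as many genes as the real one. For ref2-1 against wild type it called 4915 genes and the highest other split 6, for med5 against wild type 155 and 10, and for ref5-1 med5 against med5 2077 and 250. The highest other split called 0 genes in edgeR in the remaining comparisons of pairs. These were ref5-1 against wild type (1735 in the real split, 2421 genes at an unadjusted p under 0.05 in the other), ref5-1 med5 against ref5-1 (2149, 2584), ref2-1 med5 against ref2-1 (1773, 2385), ref2-1 med5 against med5 (3238, 2155) and ref5-1 against ref2-1 (4258, 2775). Among 100 groupings for the interaction with ref5-1, 8 called at least its 18 genes and the highest other called 1063. For ref2-1, 2 of 100 called at least its 149 genes and the highest other called 400. The counts of 1063 and 400 point to a structure of the samples. These groupings mix all 12 libraries of 4 genotypes, so the differences between genotypes enter them, and they say nothing on chance for either interaction.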

How the results depend on the processing

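Thinning, leaving out the third libraries and leaving out single libraries in the list tests were chosen after the data were seen. Counts of calls stayed within 1.5 times under RLE scaling, without the filter on low counts and with thinning in all 13 counts. DESeq2 moved med5 against wild type to 500 and the interactions to 126 (ref5-1) and 592 (ref2-1). With only the compared libraries in the fit, and so fewer samples, ref5-1 against wild type gave 1057 calls, ref5-1 med5 against ref5-1 1166, ref5-1 against ref2-1 2816, the interaction with ref5-1 10, the overlap of ref5-1 and ref2-1 calls 503 and the calls of ref5-1 kept without MED5 446. A minimum absolute log2 fold change of 1, stricter by construction, left 387 (ref5-1), 1216 (ref2-1), 64 (med5), 568 and 345 (med5 in the ref5-1 and ref2-1 backgrounds), 617 and 618 (ref5-1 and ref2-1 without MED5), 1306 (ref5-1 against ref2-1), 67 (interaction with ref2-1), 123 (overlap), 234 and 372 (kept). Without the third libraries of wild type and med5, med5 against wild type had 69 calls and the interaction with ref2-1 65. With the replicate number as a block the interaction with ref2-1 had 297 calls, and no other count moved by over 1.5 times. Same-numbered libraries of different genotypes correlated between −0.193 and 0.348. Each wild type library correlated best with its own number in 3 of 3 cases for ref5-1 med5 and in 0 for ref2-1 med5. With 3 libraries per genotype these values cannot decide whether the numbers pair the samples. Leaving out 1 library gave 716 to 1695 calls (ref5-1), 3585 to 4551 (ref2-1), 52 to 184 (med5), 897 to 2216 and 762 to 1468 (med5 in the ref5-1 and ref2-1 backgrounds), 1078 to 2079 and 1578 to 2579 (ref5-1 and ref2-1 without MED5), 3072 to 4030 (ref5-1 against ref2-1), 10 to 33 and 38 to 475 (interactions), 313 to 881 (overlap), and 448 to 785 and 951 to 1547 (kept). With 1 library left out, the remaining pair is tested with the spread shared by all genotypes. Why the counts moved was otherwise not tested.

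Of 547 called values of named genes, 0 reversed under any alternative run. DESeq2 lost 3 of these calls, RLE scaling 4, no filter 42, the compared libraries alone 99 of 543, leaving out the third libraries of wild type and med5 66 of 339, the block 20, thinning 26 and the minimum size 197; 189 lost a call without at least 1 library. Of the 105 list calls 3 held with an estimated correlation and 30 were lost without at least 1 library. Fry called 68 lists, 64 of them among the 105 and 0 in the interactions, and the block gave 108, with 103 among them. Another scaling shifted the median of all genes by at most 0.0131, and the sign of 3 list medians near 0. At the lowest depth, 19578169 counts, genes under 1 CPM rest on few reads.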

Other observations

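The values of 3 cytokinin response regulator genes follow, with no test of their family and without its other members. ARR15, ARR6 and RR16 were at 13.5 ± 0.461 CPM, 16.8 ± 2.40 CPM and 10.6 ± 1.18 CPM in wild type and at 4.46 ± 0.566 CPM, 9.26 ± 1.47 CPM and 5.50 ± 0.675 CPM in ref5-1 (edgeR, adjusted p = 2.28e-05 for ARR15, 0.00232 for ARR6 and 0.00112 for RR16). ARR6 and RR16 in this comparison, and the levels in other genotypes that follow, were chosen after their values were seen and were not run with libraries left out. In ref2-1 they were at 6.64 ± 1.42 CPM, 18.7 ± 1.38 CPM and 7.87 ± 1.93 CPM. FSD1 was at 271 ± 61.0 CPM in ref2-1 and 184 ± 91.3 CPM in ref2-1 med5. The lipid-transfer protein gene LTP4 (AT5G59310) was at 0.0909 ± 0.0624 CPM in wild type, 8.4 ± 4.04 CPM in ref5-1, 14.2 ± 5.46 CPM in ref5-1 med5, 0.193 ± 0.142 CPM in ref2-1 and 0.597 ± 0.261 CPM in ref2-1 med5. MLP34, of the major latex protein family, reached 14.4 ± 4.00 CPM in ref5-1 and 12.3 ± 2.33 CPM in ref5-1 med5 from 0.855 ± 0.173 CPM in wild type. AT4G08093 was at 0.131 ± 0.130 CPM in wild type, 0.168 ± 0.111 CPM in med5, 11.3 ± 1.13 CPM in ref5-1 and 13.1 ± 1.3 CPM in ref2-1.

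The camalexin gene CYP71B15 (AT3G26830), the last enzyme of its pathway, varied widely between libraries. It was at 0.760 ± 0.468 CPM in wild type, 0.528 ± 0.0803 CPM in ref5-1, 9.72 ± 6.78 CPM in ref2-1, 27.1 ± 40.3 CPM in ref5-1 med5 and 7.69 ± 2.75 CPM in ref2-1 med5. The jasmonate list had a median log2 fold change of −1.28 in ref2-1 med5 against ref2-1 (camera adjusted p = 1.17e-05, and adjusted p = 0.528 with an estimated correlation). Of its 23 genes edgeR called 0 over all genes (2 without ref2-1 replicate 2) and 0 adjusted over the list alone, DESeq2 called 3, and 12 had an unadjusted p under 0.05. PR1 varied between libraries of med5, at 5.75, 14.1 and 109 CPM, beside 0.160, 0.188 and 0.493 CPM in wild type.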
